A study of Mus musculus with 12 samples.

How the data were processed

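Single cells of exorbital lacrimal glands from mice of 4 months were profiled as 12 libraries: 4 of BALB/cJ females, 4 of BALB/cJ males, 2 of MRL/MpJ-Fas<lpr>/J females (MRL/lpr below) and 2 of NOD.B10Sn-H2<b>/J males (NOD.H2b below). The deposited values are UMI counts per gene and barcode; a count is the number of distinct molecules. Per the submitters' processing notes, the counts were made with Cell Ranger 3.0.1 against mm10 (GRCm38), and per the labels' protocols the libraries were made with the 10x Genomics version 2 chemistry for 3′ ends. How the authors set the number of barcodes to keep is not given in the sources used here. The lowest UMI count of a deposited barcode was 301 to 306 in every library, so the deposited barcodes had passed a limit before deposit. The matrix held 27998 genes, of which 27645 IDs matched the vM21 annotation; all 252 genes named by the rules below matched. Coordinates are GRCm38, counted from 1.

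The labels do not say that the replicates of a group were separate animals. P-values therefore measure the spread between libraries, which may be technical. The library codes fall in 2 sets: 43 to 50 (replicates 1 and 2 of all groups) and 55 to 58 (replicates 3 and 4 of BALB/cJ). Each model strain was compared with BALB/cJ of the same sex. Strain background, the lpr mutation or the H2 haplotype, and disease are therefore one difference that this design does not separate.

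Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from mitochondrially encoded genes. Doublets were scored per library with Scrublet (in scanpy 1.11.5), and the highest-scoring cells were removed at 0.8% per 1000 cells, which took 1.34 to 6.13% of the cells; Scrublet's automatic threshold marked 0 to 47 cells per library. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 40 principal components were used, and cells were clustered with the Leiden algorithm (leidenalg 0.10.2; 15 neighbours, resolution 1.0, no batch integration) into 36 clusters. A cluster took the name of a class when at least 3 of that class's listed markers were at least 2-fold above the other cells and in at least 20% of its cells. The 10 leading genes of each cluster were also read. Markers of neutrophils, mast cells, erythroid cells, adipocytes, lymphatic endothelium and salivary gland were listed too, and no cluster took any of these 6 names. A cluster whose leading genes held more markers of another class stayed unnamed. The Krt14-high epithelial class was an exception to these rules, named after the data were seen. It covers 2 clusters with raised Krt14 and Krt17 but without raised Acta2 or Cnn1. This class had no marker list of its own, and 3 leading genes of each cluster were markers of a listed class. The new name replaced the outcome of the rules.

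UMI counts were summed per library and class where a library held at least 20 cells of the class. There were 8 classes with enough libraries for gene tests. The T cell class used 11 libraries, without BALB/cJ male replicate 2. Genes were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood test) in 1 fit of all 4 groups, so that the groups of 2 libraries shared an estimate of the spread with the rest. The 3 contrasts were BALB/cJ males minus females (4 against 4), MRL/lpr females minus BALB/cJ females (2 against 4), and NOD.H2b males minus BALB/cJ males (2 against 4). A 4th contrast tested, in acinar cells, whether the 2 model strains differed from their own controls by different amounts. Adjusted p-values are Benjamini-Hochberg values within class and contrast, with the threshold at 0.05. CPM values use the TMM-scaled library size, as mean ± SD over libraries. Where the lower group had 0 UMIs, the fold is given as at least the value that 3 UMIs over that group would give; where it had 1 to 3, the ratio comes with a 95% counting interval.

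Shares of 14 classes were tested with edgeR on cell counts, with the log of the library's cells as offset. The immune share per library was tested by exact permutation, which at 2 against 4 cannot go below p = 0.0667. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over 122 pairs of list and class per contrast; a list needed 5 measured members. The lists were, with members in the matrix: type I interferon response (31), interferon gamma response outside the H2 genes (24), antigen presentation outside the H2 genes (18), H2 genes (18), unfolded protein response (23), immediate early and dissociation genes (30), chemokines and cytokines (35), tear and secretory proteins (33), fluid secretion machinery (37), steroid-responsive genes (26), extracellular matrix and fibrosis (32), proliferation (20), T cell activation and exhaustion (32), nuclear oxidative phosphorylation genes (39), secretoglobins (34), lipocalins with major urinary proteins (35), exocrine gland-secreted peptides (15), kallikreins (27), ribosomal proteins (85), mitochondrially encoded genes (13), sex chromosome genes (10) and the lpr target Fas.

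The tests, contrasts, lists, class markers and the rule for named genes were written down before the data were examined. Named genes were the 8 highest and 8 lowest log2 fold changes in acinar cells and the 3 highest and 3 lowest in each other class, among genes past the threshold with an average log2 CPM of at least 4, without overlap between the CPMs of the 2 groups' libraries, and with a CPM in the class at least that of all other cells of the same libraries. The last condition, called "own class" below, was meant to keep out RNA that leaked from other cells. The other cells were pooled by UMIs, so for classes other than acinar the pool was mostly acinar RNA. Acinar cells held 56461859 of 63287143 kept UMIs in BALB/cJ female replicate 1 and 23096418 of 44809988 in MRL/lpr replicate 2. In those classes the condition therefore keeps out mainly acinar RNA, and RNA leaked from other classes can pass it. From each list, up to 4 passing members with the largest change were added, without the own class condition. Gene models without a name, ribosomal, mitochondrially encoded, immunoglobulin and T cell receptor segment genes were left out of the first part, and Fas was named in every library. A few single genes are not reported here.

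Median UMIs per kept cell ranged from 1787 to 4358.5, with NOD.H2b replicate 1 at 18596. The precision was tested on simulated data. Counts were drawn from each gene's mean over all libraries, its dispersion and the real library sizes, with 200 genes changed by known folds, 50 per fold. All other genes had the same mean in every group. The simulation therefore does not cover contrasts in which many more genes, or large shares of the UMIs, change. In acinar cells, changes of 4-fold were recovered for 92% of the genes in the sex contrast, 86% in the MRL/lpr contrast and 84% in the NOD.H2b contrast; at 1.5-fold these were 28%, 4% and 14%. False calls were 5.33%, 4.92% and 4.48% of the calls. In macrophages, 4-fold changes were recovered for 94%, 96% and 58%, and false calls were 6.84%, 7.35% and 4.55%.

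Reads were mapped to the C57BL/6J reference. BALB/cJ carries H2 haplotype d, MRL haplotype k and NOD.H2b haplotype b, that of the reference, so polymorphic H2 genes can gain or lose counts by mapping alone. Families of near-identical copies (Scgb, Mup, Obp, Esp, Tpm3-rs7, Hist1h2al, Ccl19) share reads that the counting step may have dropped or assigned by strain variant. The lpr insertion lies in an intron of Fas, away from the 3′ tag.

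Alternatives tried were DESeq2 1.42.0 in place of edgeR, upper-quartile scaling, no filter on low counts, fits of only the 2 groups compared, only libraries of the same code set, each library left out, the replicate number as a block, at least 1000 UMIs or at most 10% mitochondrial UMIs per cell, no doublet removal, resolution 0.5 (30 clusters), at least 50 cells per library, and TMM scaling of cell counts. Figures and cell steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9; tests used R 4.3.3 with the data.table package, version 1.17.8.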

Results

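The 12 libraries held 40696133 (BALB/cJ female replicate 4) to 93169593 (NOD.H2b replicate 1) deposited UMIs. After filtering, BALB/cJ females kept 4366, 4527, 3818 and 2482 cells, BALB/cJ males 4249, 3914, 2128 and 1648, MRL/lpr females 7188 and 6173, and NOD.H2b males 4607 and 3103. BALB/cJ female replicates 2 and 4 and BALB/cJ male replicate 2 had a median of only 99, 106 and 105 genes per deposited barcode, against 220 to 1074.5 in the other libraries. Xist, the RNA of the inactive X chromosome, stood at 169 to 764 CPM in the female libraries and at 0 to 8 UMIs in the male libraries. Ddx3y, on the Y chromosome, had 0 UMIs in the females and 446 to 777 UMIs in the males, so the sex labels held. Fas was detected in every library (63 to 392 UMIs). Over all cells, whose mix of classes differed, it stood at 4.41 and 8.75 CPM in MRL/lpr and at 3.33, 3.71, 6.26 and 3.80 CPM in BALB/cJ females. Within classes, looked at after seeing the data, it went both ways. It was lower in MRL/lpr in Krt14-high cells (59.08 and 106 against 156.9 to 284.2 CPM, adjusted p = 0.000779) and endothelial cells (32.86 and 21.53 against 37.61 to 112.1, adjusted p = 0.0268). It was higher in ductal cells (4.818 and 9.333 against 0.941 to 2.898, adjusted p = 0.0237), and acinar, myoepithelial, fibroblast and macrophage values did not pass.

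Acinar cells of the 2 sexes formed separate clusters. BALB/cJ females filled clusters 0 and 5, and BALB/cJ males clusters 31, 32 and 33. MRL/lpr females filled cluster 22 and part of 5, and NOD.H2b males cluster 35 and part of 32 and 33. Ductal, myoepithelial, fibroblast, plasma and Krt14-high cells also split by sex (10 and 27, 4 and 26, 6 and 30 beside the shared cluster 2, 16 and 28, 3 and 29). Comparisons between males and females of these classes were therefore between different clusters. Macrophages and monocytes filled cluster 1 in all groups, cluster 23 mainly in males and cluster 21 in MRL/lpr. Cluster 7 came mainly from BALB/cJ females and held only 13 and 0 cells of the MRL/lpr females. T cells (19 and 25) and endothelial cells (9 and 11) shared clusters. Unnamed cells were 6.55 ± 4.49% in BALB/cJ females, 2.74 ± 1.59% in BALB/cJ males, 8.41 ± 3.63% in MRL/lpr and 1.01 ± 1.03% in NOD.H2b. They included an immune-like cluster led by Ccr7, Myb and Txk, with 646 cells in MRL/lpr replicate 1, 200 in replicate 2 and 3 in NOD.H2b replicate 2.

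MRL/lpr glands were filled with immune cells. T cells made up 29.8 ± 1.24% of MRL/lpr cells and 1.02 ± 0.335% of BALB/cJ female cells (edgeR adjusted p = 0.00565). B cells (adjusted p = 0.0131) and plasma cells (5.84 ± 2.90% against 0.565 ± 0.813%, adjusted p = 0.0454) also rose. Both calls were lost without MRL/lpr replicate 2. The plasma cell call was also lost without MRL/lpr replicate 1, without BALB/cJ female replicate 1 or 2 and with only the 2 groups compared, and the B cell call with the same library set only and without the 3 libraries of few genes per barcode. Acinar cells fell to 4.30 ± 0.250% from 21.0 ± 7.54% (adjusted p = 0.00293), fibroblasts to 5.97 ± 0.354% from 14.7 ± 1.18% (adjusted p = 0.00293) and Krt14-high cells to 2.12% from 7.09% (adjusted p = 0.00295). These are shares of one total, so more immune cells alone would lower the share of every other class. The falls therefore do not show a loss of cells. With at least 1000 UMIs per cell only the T cell, B cell and acinar calls were kept. Macrophages stood at 15.9% against 10.8% (adjusted p = 0.133). All immune classes together were 57.7 ± 5.86% of MRL/lpr cells (53.55 and 61.83%) and 16.8 ± 3.17% of BALB/cJ female cells, a difference of 40.88 points. The exact permutation p was 0.0667, the smallest that 2 against 4 can reach.

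In NOD.H2b males the B cells rose to 2.37 ± 2.80% from 0.0956% (adjusted p = 0.00776). Fibroblasts (5.06 against 10.1 ± 0.906%), myoepithelial cells (3.80 against 9.25%) and Krt14-high cells (2.32 against 6.26%) fell (each adjusted p = 0.00776). Pericytes fell too (0.809 against 2.31%, adjusted p = 0.049). That call was lost without BALB/cJ male replicate 1, 3 or 4 and with the replicate number as a block. BALB/cJ male replicate 2 (0.7154%) lay between the NOD.H2b libraries (0.6512 and 0.9668%). None of the 14 classes passed with only the 2 groups compared, with the same library set only, or with at least 1000 UMIs per cell. Without NOD.H2b replicate 1 only 1 class passed, the B cells, and without NOD.H2b replicate 2 the B cells were lost and 4 classes passed. T cells were 0.847% of replicate 1 and 5.48% of replicate 2, so the 2 NOD.H2b libraries differed in infiltrate. Acinar cells were 54.6 ± 14.5% of NOD.H2b and 34.4 ± 11.1% of BALB/cJ male cells (adjusted p = 0.2). A larger acinar share alone would lower the shares of the other classes. Fibroblasts, myoepithelial and Krt14-high cells also passed as lower among cells outside the acinar class, and pericytes did not. That denominator was chosen after seeing the data. The immune share was 19.9 ± 8.34% (14.02 and 25.81%) against 19.5 ± 6.05%, a difference of 0.4354 points (exact permutation p = 0.933), which turned to -5.46 without NOD.H2b replicate 2 and to -2.32 without BALB/cJ male replicate 2. The immune share was also taken among cells outside the acinar class, a comparison chosen after seeing the data. It was 43.1 ± 4.62% against 29.1 ± 5.04%, a difference of 14 points (exact permutation p = 0.0667, the smallest possible).

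Between the sexes no class share passed (0 of 14 by edgeR with Benjamini-Hochberg adjustment, 4 at unadjusted p < 0.05). Those 4 were dendritic cells (2.90 ± 1.09% in males, 1.38 ± 0.501% in females, adjusted p = 0.123), fibroblasts (adjusted p = 0.123), myoepithelial cells (9.25 against 13.3%, adjusted p = 0.145) and plasma cells (3.24 ± 1.01 against 0.565 ± 0.813%, adjusted p = 0.145). With TMM scaling of the cell counts, and without BALB/cJ male replicate 2, 1 class passed. Immune cells were 2.669 points higher in males (exact permutation p = 0.429), 5.424 without BALB/cJ male replicate 2 and 0.8451 without male replicate 3. Among cells outside the acinar class they were 29.1 ± 5.04% in males and 21.2 ± 2.34% in females, a difference of 7.951 points (exact permutation p = 0.0571), a comparison chosen after seeing the data.

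**Figure D1:**
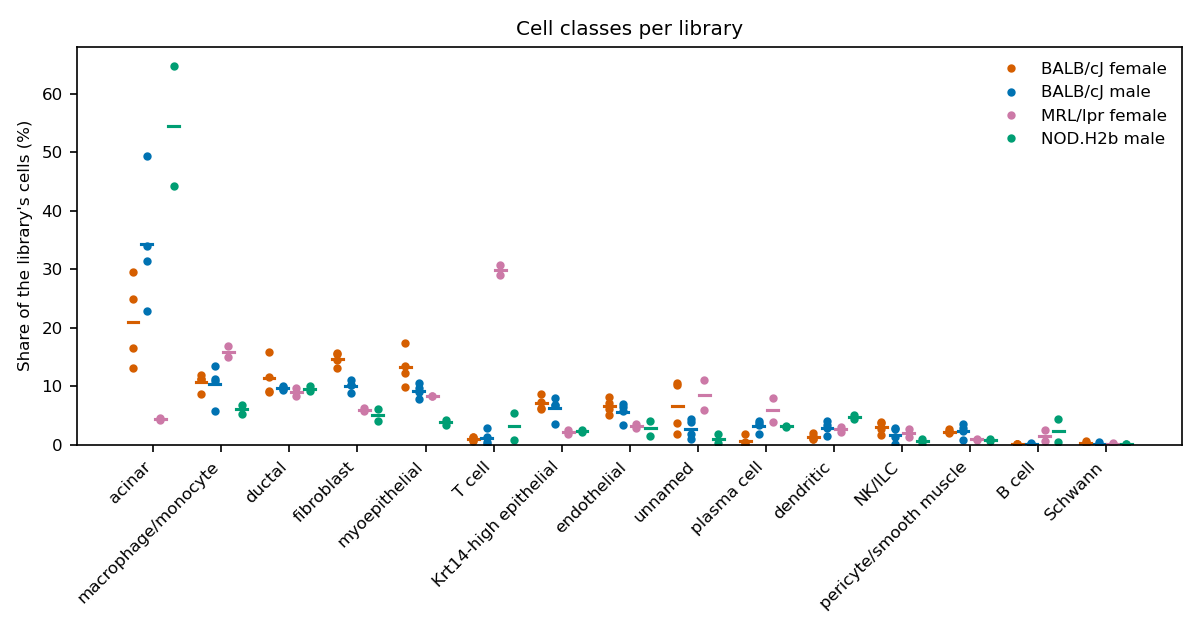
Share of each library's cells in each class, by group. Points are libraries and bars are group means.

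Male and female BALB/cJ acinar cells expressed different tear protein genes. Male cells expressed the secretoglobins of the androgen-binding protein family Scgb2b3, Scgb1b3 and Scgb2b12, the male tear pheromone Esp1, the major urinary protein Mup4 and the protease inhibitor-like Wfdc12. Female cells expressed the lipase-related Pnliprp1, the odorant-binding lipocalins Obp1a and Obp1b, the mucin-like Mucl2 and the endonuclease Dnase1. Secretoglobins took 59.3 ± 0.983% of acinar UMIs in males and 32.1 ± 1.08% in females, lipocalins with major urinary proteins 7.86 ± 2.06 and 17.4 ± 1.62%, and exocrine gland-secreted peptides 4.25 ± 0.450 and 3.46 ± 0.228%. The most abundant transcripts in females were Scgb1b2 (15.8 ± 1.23% of acinar UMIs), Mucl2 (11.6%), Scgb2b2 (11.4%) and Obp1a (11.4%). In males they were Scgb2b7 (12.4 ± 2.57%), Scgb1b7 (10.4%), the gene model Gm1553 (8.14%), Scgb2a2 (7.04%), Scgb2b24 (6.51%) and Mup4 (5.57%).

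**Figure D2:**
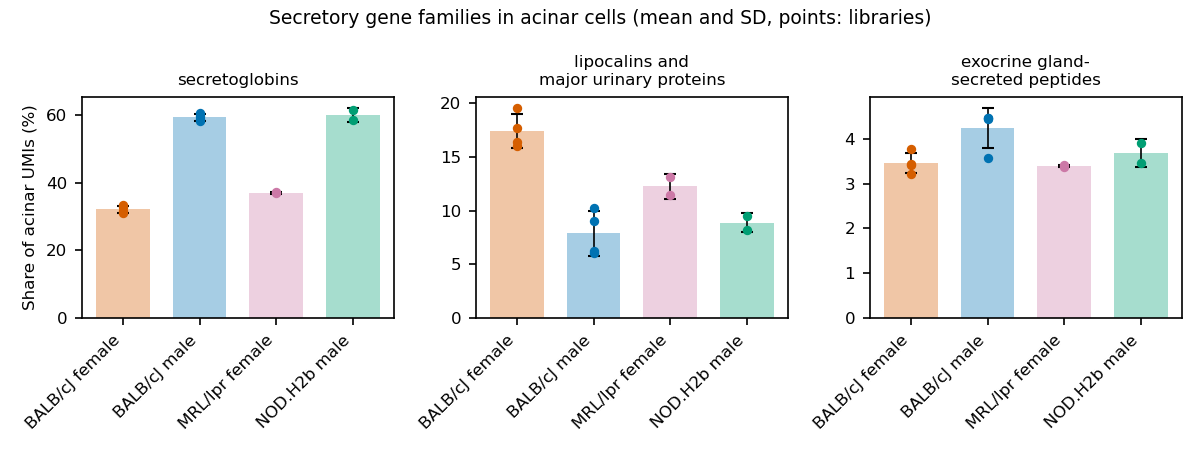
Share of acinar UMIs from secretoglobins, lipocalins with major urinary proteins, and exocrine gland-secreted peptides, as mean and SD per group.

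Of 11585 genes tested in acinar cells, 3360 passed (1804 higher in males, 1556 higher in females), 1444 of them at 2-fold or more and 324 in their own class (233 and 91). The secretoglobins led. Scgb2b3 (ENSMUSG00000078754, 7:31359038–31362072) rose by 15.60 log2 units (adjusted p = 1.05e-09). Scgb1b3 (ENSMUSG00000095257, 7:31375592–31376916) rose by 14.17 (adjusted p = 2.47e-12), from 2.79 ± 1.95 CPM in females to 51940 ± 10150. Scgb2b12 rose by 15.12 (adjusted p = 1.13e-05) and Scgb2b17 by 13.04 (adjusted p = 0.000349), with 4 UMIs in females. Scgb1b10 was higher by a ratio of 8170 (1470–323000) and the glutamate ligase gene Rimklb by 11800 (2120–467000). Mrap (ENSMUSG00000039956, 16:90738207–90749785), the accessory protein of the melanocortin 2 receptor, had 81.7 ± 13.6 CPM in males and 0 in females, at least 4970-fold (adjusted p = 7.43e-14). The cytochrome gene Cyp2j13 had 42.1 ± 6.77 CPM against 0, at least 2600-fold (adjusted p = 1.02e-13). All of these calls held without each single library.

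On the female side, Pnliprp1 (ENSMUSG00000042179, 19:58728887–58744169) stood at 1459 ± 491 CPM in females and was lower in males by a ratio of 266000 (47800–10500000, adjusted p = 5.03e-09). Asgr1, a subunit of the asialoglycoprotein receptor, was lower by a ratio of 1410 (482–6840). Obp1b (ENSMUSG00000067679, X:78186777–78192292) fell by 9.43 log2 units in males (adjusted p = 5.19e-05; 69.1 ± 56.4 against 47690 ± 19270 CPM). Obp1a fell by 2.35 (adjusted p = 1.56e-05; 19400 ± 10580 against 98560 ± 8259). Phyh, a peroxisomal hydroxylase of phytanoyl-CoA, fell by 5.27 (adjusted p = 1.73e-09), Esp36 by 3.70 (adjusted p = 0.000223), and Dnase1 by 3.15 (adjusted p = 2.17e-05). Mucl2 (ENSMUSG00000036925, 15:103895855–103899312) fell by 2.71 (adjusted p = 9.23e-07; 15470 ± 5636 against 101600 ± 16960). Between the 2 library sets, each fitted alone, 1638 and 2233 of 10396 genes passed. Both sets shared 1268, all in the same direction, where 352 would be shared if the sets were independent. Log2 fold changes of the 2 sets correlated at 0.916.

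**Figure D3:**
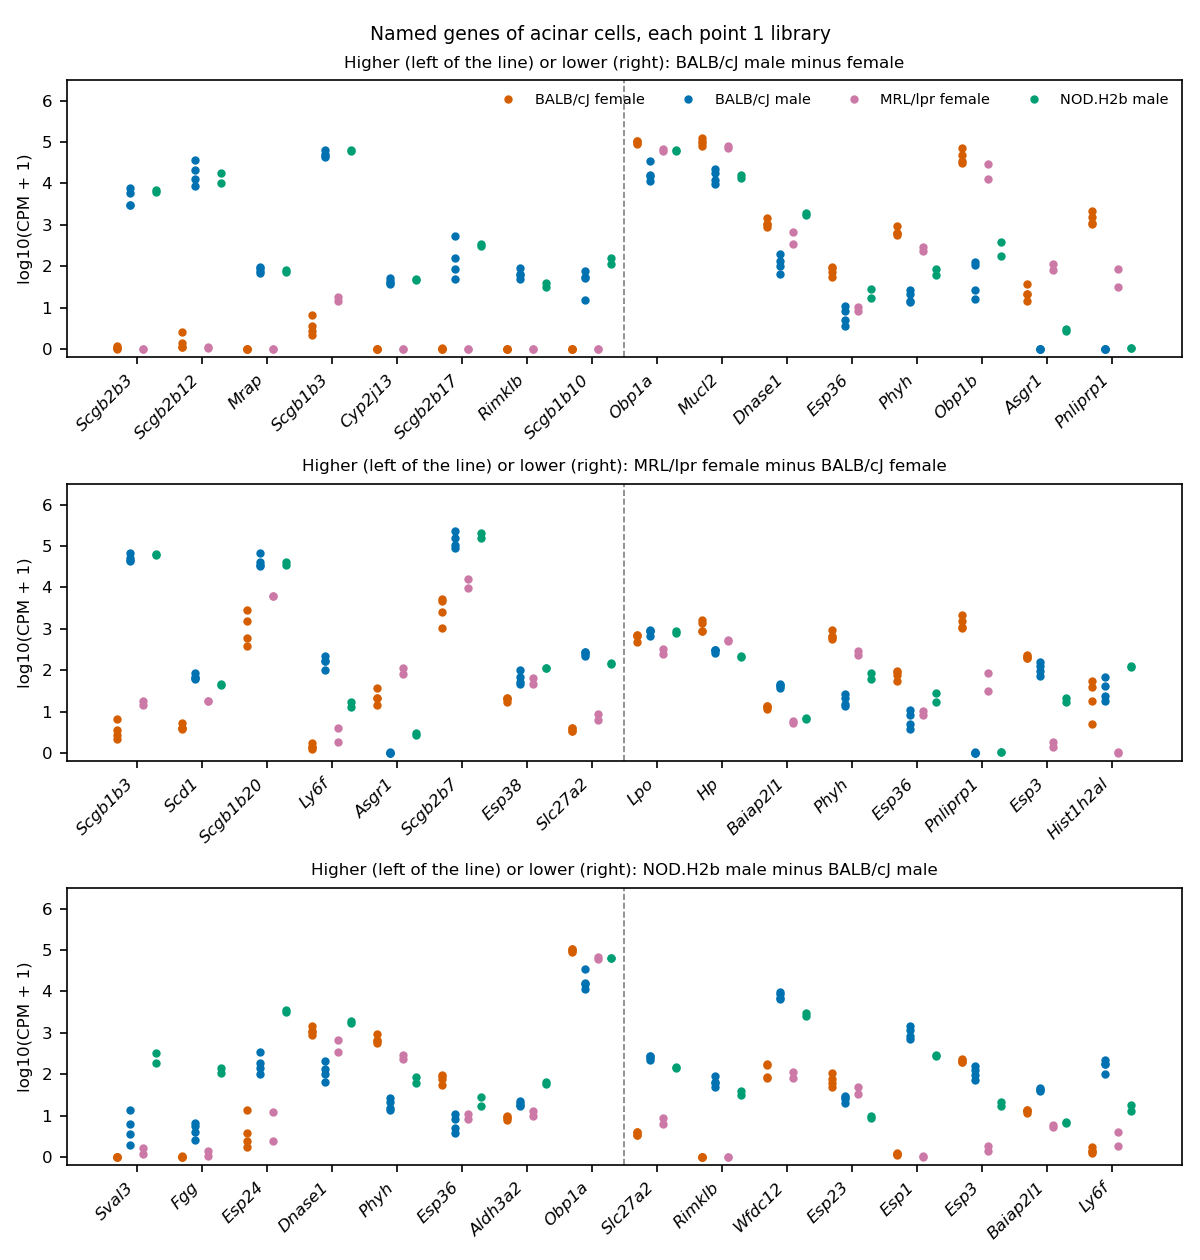
CPM per library of 16 genes per contrast in acinar cells, as log10 of CPM plus 1. The dashed line separates genes higher from genes lower in the first group of the contrast.

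Among the fixed lists in acinar cells, the secretoglobins rose as a group. Of 27 members 23 rose and 2 fell, also 23 and 2 adjusted over the list alone (median 5.46, camera adjusted p = 1.67e-24, adjusted p = 0.0312 with an estimated correlation). The other secretory families changed in both directions. Of 14 exocrine gland-secreted peptides 6 rose and 6 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.445). Esp1 (ENSMUSG00000073396, 17:40727120–40731782) rose by 12.48 (adjusted p = 4.28e-14; 1034 ± 329 against 0.184 CPM). Esp24 rose by 5.46 (adjusted p = 0.00541) and Esp16 by 4.44 (adjusted p = 0.00175). Of 10 lipocalins and major urinary proteins 6 rose and 2 fell (the same adjusted over the list alone, median 3.43, camera adjusted p = 0.369). Mup4 (ENSMUSG00000041333, 4:59956804–59960710) rose by 4.86 (adjusted p = 0.000604; 61250 ± 3811 against 2108 ± 2322) and Mup5 by 4.48. Of 18 tear and secretory proteins 5 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.729). Wfdc12 (ENSMUSG00000042845, 2:164189231–164190608) rose by 5.99 (adjusted p = 4.06e-11; 7967 ± 1335 against 125.2 ± 50.9).

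Single genes of other lists passed in acinar cells, while most of these lists as a whole did not. Apart from Prlr, the pooled other cells of the same libraries had a higher CPM of each gene named here. CPM is a share of RNA and not an amount per cell. RNA from other cells stayed open for these genes. The prolactin receptor Prlr fell by 3.27 in males (adjusted p = 2.25e-09). Hsd17b11, a steroid dehydrogenase, rose by 3.95 (adjusted p = 3.53e-12) and the glucocorticoid target Fkbp5 by 2.84 (adjusted p = 1.14e-07). In the steroid-responsive list 4 rose and 6 fell of 21 (4 and 7 adjusted over the list alone, camera adjusted p = 0.963). The median of that list was 0, the mean -0.051 and the test pointed up. In the fluid secretion machinery 7 rose and 9 fell of 28 (7 and 9 adjusted over the list alone, adjusted p = 0.963). In the unfolded protein response 6 rose and 5 fell of 23 (10 and 5 adjusted over the list alone, adjusted p = 0.739). Xbp1 fell by 1.03 (adjusted p = 1.78e-05), and Ddit3 (0.91) and Edem1 (0.69) rose. Of 29 immediate early and dissociation genes 11 rose and 3 fell (12 and 4 adjusted over the list alone, adjusted p = 0.139). Klf2 rose by 3.20 (adjusted p = 2.82e-06), Fosl2 by 2.09 and Klf4 by 1.65, and Egr2 fell by 1.85. Of 82 ribosomal protein genes 2 rose and 25 fell (2 and 26 adjusted over the list alone, median -0.35, adjusted p = 0.000992, adjusted p = 0.992 with an estimated correlation), such as Rpl7a (-0.76) and Rpl23a (-0.71).

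Immune lists moved little in the acinar cells of healthy males. The pooled other cells of the same libraries had a higher CPM of each gene named here, so RNA from other cells stayed open. Type I interferon genes rose for 5 and fell for 1 of 25 (5 and 1 adjusted over the list alone, camera adjusted p = 0.111), with Oas1a at 4.12. Interferon gamma genes rose for 2 of 18 (adjusted p = 0.57), Irf8 at 1.95 and Irf1 at 1.33. Antigen presentation genes rose for 3 and fell for 1 of 18 (adjusted p = 0.495), with B2m at 4.34, Calr at 1.01 and Canx at -0.55. H2 genes rose for 1 of 14 (adjusted p = 0.653), a call for H2-K1 (1.16) that was lost without BALB/cJ male replicate 4 (adjusted p = 0.0521). Chemokines and cytokines rose for 5 and fell for 4 of 26 (adjusted p = 0.556). Extracellular matrix genes rose for 2 and fell for 1 of 28 (adjusted p = 0.997), with Tgfb1 at 1.39. The median of the matrix list was 0.198, the mean 0.177 and the test pointed down. Proliferation rose for 1 of 20 (adjusted p = 0.643) and T cell activation for 0 of 7 (adjusted p = 0.867, median 0.117, mean -0.035). Nuclear oxidative phosphorylation genes rose for 4 and fell for 3 of 39 (adjusted p = 0.739), with Ndufa1 at 0.83. Mitochondrially encoded genes passed for 0 of 13 (adjusted p = 0.873). Kallikreins had under 5 measured members in each class and were not tested as a list. Of the 68 named acinar results of this contrast, 64 kept their call without each library.

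The sexes also differed outside the acini, most in fibroblasts and macrophages. Male fibroblasts expressed the complement gene C7, the ecto-nucleotidase Nt5e and Aldh1a2, which makes retinoic acid. Female fibroblasts expressed Cyp26b1, which breaks retinoic acid down, and the growth factor-binding Igfbp3. C7 (ENSMUSG00000079105, 15:4988762–5063740) had 75.2 ± 15.4 CPM against 0, at least 168-fold (adjusted p = 2.08e-11). Nt5e was higher by a ratio of 204 (69.0–997), and Aldh1a2 (ENSMUSG00000013584, 9:71215789–71296243) rose by 5.46 (adjusted p = 2.75e-10). Cyp26b1 (ENSMUSG00000063415, 6:84571414–84593908) had 0 UMIs in males and 38.3 ± 7.10 CPM in females, at least 31.9-fold (adjusted p = 4.47e-08). Igfbp3 (ENSMUSG00000020427, 11:7206086–7213923) fell by 7.91 (adjusted p = 4.78e-14; 1.76 against 519 ± 126 CPM). In fibroblasts 570 genes passed (315 up, 255 down), 532 of them in their own class. In the 2 library sets 126 and 495 passed and 102 in both, all in the same direction, where 7.9 would be shared by independence. Ductal, myoepithelial, endothelial and macrophage classes shared fewer genes. Of 20 and 80 ductal genes 13 were shared, 12 in the same direction (0.196 by independence, correlation 0.571). Of 14 and 167 myoepithelial genes 11 were shared (0.318, correlation 0.544), of 19 and 51 endothelial genes 12 (0.209, 0.587) and of 26 and 185 macrophage genes 20 (0.873, 0.638), all in the same direction. Sex chromosome genes were not left out of these counts and would be shared between any sets of males and females. Acinar RNA in the droplets could be shared as well. Sharing above independence therefore does not by itself show further sex differences of these classes.

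Male macrophages held more of the chemokine Ccl8 (ENSMUSG00000009185, 11:82115185–82116799; 2.70, adjusted p = 0.00422; 6559 ± 1470 against 1006 ± 420 CPM), the galectin Lgals3 (ENSMUSG00000050335, 14:47367751–47386160; 2.20, adjusted p = 1.17e-10) and the dipeptidase Dpep2 (2.29, adjusted p = 0.00022). They held less of the chemokine receptor Ccr1 (-3.83, adjusted p = 0.00537), Ptgs1 (-3.37, adjusted p = 3.91e-05) and Bmp2 (-3.10, adjusted p = 2.87e-05). In macrophages 163 genes passed (60 up, 103 down), 143 of them in their own class, between clusters that differ by sex in part. The count was 87 without BALB/cJ female replicate 4. Chemokines and cytokines fell for 5 and rose for 1 of 21 (10 and 1 adjusted over the list alone, camera adjusted p = 5.63e-08, adjusted p = 0.338 with an estimated correlation). Interferon gamma genes fell for 2 of 18 (7 adjusted over the list alone, adjusted p = 0.000276, adjusted p = 0.382 with an estimated correlation) and H2 genes for 2 of 15 (adjusted p = 0.00395, adjusted p = 0.517 with an estimated correlation).

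In ductal cells the placental growth factor Pgf rose by 2.87 in males (adjusted p = 1.02e-07; 62.7 ± 10.8 against 8.24 CPM). The cytochrome Cyp2b10 rose by 1.54 (adjusted p = 0.000201). In myoepithelial cells Mlph (2.45, adjusted p = 0.000136) and Rab27b (2.05, adjusted p = 0.000156), both of the granule transport machinery, rose, and Emb (-2.06, adjusted p = 5.43e-05) and the matrix protein Fmod (-2.02, adjusted p = 4.31e-05) fell. In endothelial cells Efhd1 rose (2.04, adjusted p = 0.00196) and Irx3 (-2.96, adjusted p = 0.00418), the alkaline phosphatase Alpl (-2.84, adjusted p = 0.000242) and Scgb3a1 (-2.31, adjusted p = 6.03e-05) fell. In Krt14-high cells the protease inhibitor Timp4 rose (2.82, adjusted p = 0.000507) and the endothelin Edn1 fell (-3.45, adjusted p = 0.000358). Passing genes numbered 64 in ductal, 119 in myoepithelial, 60 in endothelial, 9 in T cells and 50 in Krt14-high cells, sex chromosome genes included. Of these, 49, 105, 47, 2 and 39 were in their own class. In T cells 7 genes were higher in males, and 0 of them were in their own class. Single libraries moved the counts of passing genes. The myoepithelial count was 76 without BALB/cJ male replicate 1, 67 without female replicate 3 and 71 without female replicate 4. The endothelial count was 27 without male replicate 1 or female replicate 4. The Krt14-high count was 30 without male replicate 1 or female replicate 4 and 31 without male replicate 3. In T cells the only named gene, Ctsw (-2.47), was lost when a library was left out.

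Secretoglobins passed in all 6 of the other classes with list tests, and none of the rising members was in its own class. Of 17 members 4 rose in ductal cells (camera adjusted p = 3.33e-30, adjusted p = 0.331 with an estimated correlation) and 8 in fibroblasts (adjusted p = 5.12e-12, adjusted p = 0.418 with an estimated correlation). Interferon gamma genes fell for 3 of 18 in endothelial cells (adjusted p = 3.09e-05, adjusted p = 0.382 with an estimated correlation) and for 2 of 19 in myoepithelial cells (adjusted p = 0.000513, adjusted p = 0.66 with an estimated correlation). In myoepithelial cells 2 of 21 fluid secretion genes rose (adjusted p = 0.00796, adjusted p = 0.331 with an estimated correlation), and 2 of 18 matrix genes fell (adjusted p = 0.00472, adjusted p = 0.382 with an estimated correlation). In all, 32 of 122 pairs passed at the preset correlation, 1 with an estimated correlation (the acinar secretoglobins) and 2 by fry.

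**Figure D4:**
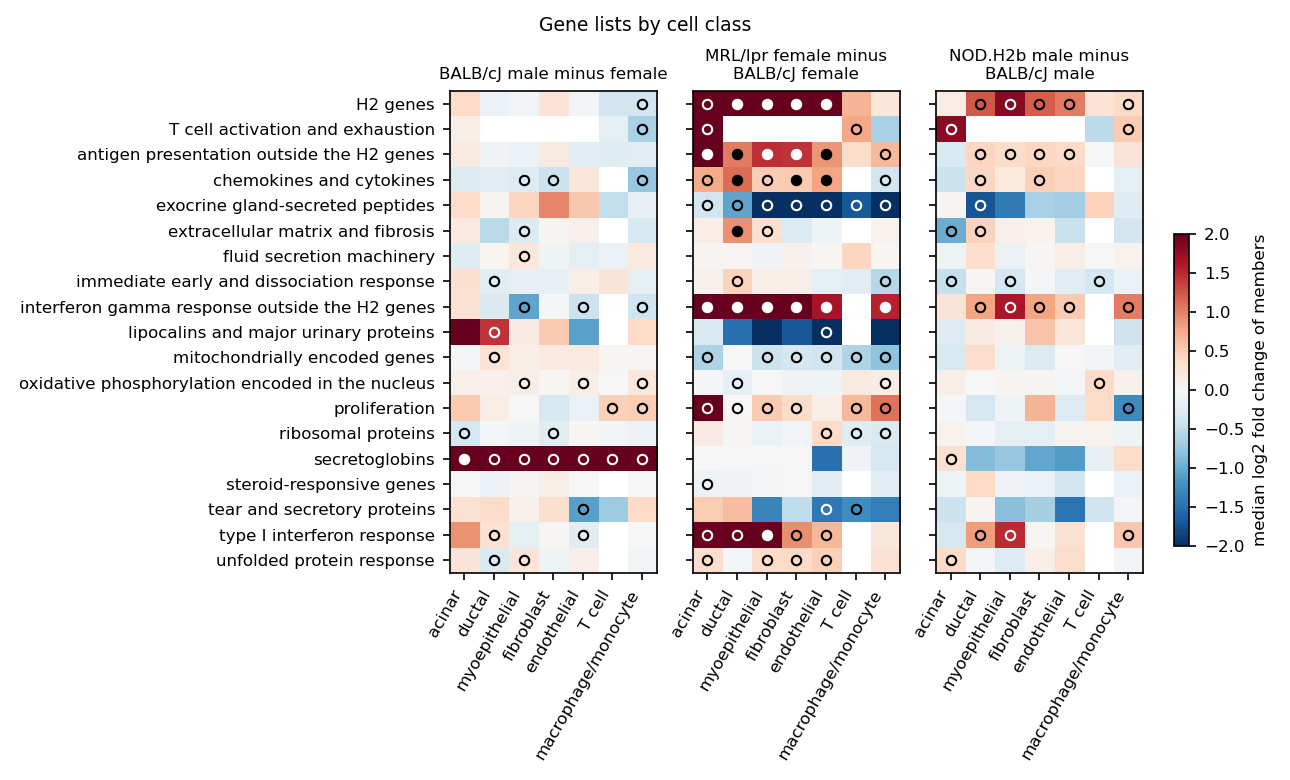
Median log2 fold change of each list in each class for the 3 contrasts, with colour ends at 2 and -2. Open circles passed camera at the preset correlation, filled circles also with an estimated correlation, and blank fields had under 5 members.

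Ductal, myoepithelial, stromal and macrophage classes of the MRL/lpr gland raised genes that interferon gamma induces. Myoepithelial cells, fibroblasts and endothelium expressed more of the guanylate-binding protein Gbp2, the immunity-related GTPases Iigp1 and Igtp, the immunoproteasome subunits Psmb8 and Psmb9, the peptide transporter Tap1 and B2m (adjusted p at most 0.000691 in each class). Ductal, endothelial and Krt14-high cells expressed more of the class II loading gene H2-DMb1. Fibroblasts, macrophages and endothelium expressed the T cell chemokine Cxcl9, and T cells expressed the inhibitory receptor Lag3 and the granzyme Gzmb. MRL/lpr acinar cells had the female tear genes Scgb1b2 (16.6% of acinar UMIs), Scgb2b2 (13.2%) and Mucl2 (10.2%) on top. Secretoglobins took 37.0 ± 0.226% of their UMIs, lipocalins 12.3 ± 1.18% and exocrine gland-secreted peptides 3.40 ± 0.0283%. They expressed less of the peptide Esp3, of Pnliprp1 and of the antimicrobial lactoperoxidase Lpo.

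In MRL/lpr acinar cells 1839 genes passed (1023 up, 816 down), 137 of them in their own class (65 and 72); without MRL/lpr replicate 2 the count was 682. Acinar genes that rose were the fatty acid desaturase Scd1 (ENSMUSG00000037071, 19:44394455–44407879; 2.39, adjusted p = 1.77e-08; 17.2 ± 0.285 against 3.30 CPM), Asgr1 (2.08, adjusted p = 0.000945; 95.8 ± 23.8 against 22.7 ± 9.57) and Scgb1b3 (2.44, adjusted p = 0.000628). Esp38 (1.52, adjusted p = 0.000858) and the acyl-CoA synthetase Slc27a2 (1.25, adjusted p = 9.07e-05) also rose. Those that fell were Esp3 (ENSMUSG00000093957, 17:40632075–40637060; -8.40, adjusted p = 1.49e-08; 209.9 ± 18.0 CPM in the controls), Pnliprp1 (-4.64, adjusted p = 0.000111; 58.5 ± 39.6 against 1459 ± 491) and Baiap2l1 (-1.41, adjusted p = 4.69e-06). So did haptoglobin Hp (-1.20, adjusted p = 0.00196) and Lpo (-1.17, adjusted p = 0.00124; 285.9 against 642 ± 120). Without MRL/lpr replicate 2, Esp36 (-3.23, adjusted p = 0.0807) and Phyh (-1.43, adjusted p = 0.101) were lost. Scgb1b20 (2.20), Ly6f (2.12), Scgb2b7 (1.92) and Hist1h2al (lower by a ratio of 892, 247–7370) were also lost in at least 1 refit. Scgb1b20, Ly6f, Scgb2b7 and Hist1h2al were lost without MRL/lpr replicate 1, Scgb1b20 and Hist1h2al also without replicate 2, Scgb1b20 also without BALB/cJ female replicate 3 and Ly6f without female replicates 2, 3 or 4. Of 71 named acinar results 38 kept their call without each library.

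Immune lists led in MRL/lpr acinar cells. None of their rising genes was in its own class, since the pooled other cells of the same libraries had a higher CPM of each. Interferon gamma genes rose for 15 of 18 (17 adjusted over the list alone, camera adjusted p = 4.82e-26, adjusted p = 0.0213 with an estimated correlation). They included Gbp2 (ENSMUSG00000028270, 3:142620602–142638008; 6.75, adjusted p = 7.16e-08; 10.4 ± 2.96 against 0.102 CPM) and Igtp (6.25, adjusted p = 6.78e-09). Iigp1 (ENSMUSG00000054072, 18:60376027–60392634; 5.62, adjusted p = 3.11e-07) and Irgm2 (5.17) followed. Antigen presentation genes rose for 14 and fell for 2 of 18 (adjusted p = 8.17e-23, adjusted p = 0.0201 with an estimated correlation). Here Psmb8 (5.49, adjusted p = 7.45e-06), Psmb9 (5.14), Tap1 (3.66, adjusted p = 2.47e-06) and B2m (ENSMUSG00000060802, 2:122147686–122153083; 4.74, adjusted p = 0.000107) led. H2 genes rose for 11 of 14 (13 adjusted over the list alone, adjusted p = 8.35e-21, adjusted p = 0.0551 with an estimated correlation). H2-K1 (4.63), H2-DMb1 (3.85) and H2-DMa (3.69) were among them. Type I interferon genes rose for 15 of 25 (21 adjusted over the list alone, adjusted p = 1.01e-15, adjusted p = 0.203 with an estimated correlation). Rsad2 (5.18) and Zbp1 (4.70) led that list. Chemokines and cytokines rose for 11 and fell for 1 of 26 (12 and 1 adjusted over the list alone, adjusted p = 1.1e-06, adjusted p = 0.21 with an estimated correlation). Ccl8 (5.90), Ccl5 (4.94) and Cxcl13 (3.07) were the chemokines that rose most. T cell activation genes rose for 4 of 7 (adjusted p = 8.25e-08, adjusted p = 0.0551 with an estimated correlation), with Nkg7 (5.32), Icos (3.18) and Tigit (at least 16.4-fold). Immune markers themselves stood at 41.9 and 66.6 CPM (of all UMIs) in the MRL/lpr acinar cells outside the cycle, against 4.29 to 11.6 in BALB/cJ females. At most 1 immune UMI was found in 135 of 296 and 62 of 276 MRL/lpr acinar cells, and in 1064 of 1089, 1299 of 1336, 461 of 498 and 334 of 412 of the BALB/cJ females. RNA of immune cells in the acinar droplets therefore stayed open for the T cell genes and chemokines.

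Cell cycle and folding genes passed as well, though the pooled other cells of the same libraries had a higher CPM of each gene named here. Proliferation genes rose for 19 of 20 in acinar cells (20 adjusted over the list alone, adjusted p = 6.36e-17, adjusted p = 0.145 with an estimated correlation). Cenpf rose by a ratio of 122 (40.9–600) and Ccnb2 by 5.35 (adjusted p = 0.00248), while Ube2c and Aurkb were lost without MRL/lpr replicate 2. Cell cycle genes stood at 7.745 CPM in the acinar cells of replicate 1 and at 90.92 in those of replicate 2, where 94.9% of these UMIs lay in 24 cells. The unfolded protein response rose for 8 of 23 (9 rose and 1 fell adjusted over the list alone, adjusted p = 0.00604, adjusted p = 0.0954 with an estimated correlation). Pdia6 (1.09, adjusted p = 2.56e-05), Creld2 (0.94, adjusted p = 0.000178) and the chaperone Hspa5 (0.75, adjusted p = 0.00197) rose. Mitochondrially encoded genes fell for 3 of 13 (6 adjusted over the list alone, adjusted p = 0.00163, adjusted p = 0.297 with an estimated correlation). Exocrine gland-secreted peptides fell for 4 and rose for 1 of 14 (5 and 1 adjusted over the list alone, adjusted p = 0.00165, adjusted p = 0.297 with an estimated correlation). Steroid-responsive genes fell for 3 of 21 (adjusted p = 0.0412, adjusted p = 0.237 with an estimated correlation), led by the metallothionein Mt1 (-2.53, adjusted p = 3e-07; 14.5 against 83.5 ± 17.7 CPM).

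Other lists did not pass in MRL/lpr acinar cells. For secretoglobins (3 rose of 27, adjusted p = 0.206) the median was -0.002 and the mean -0.035 while the test pointed up. For lipocalins (1 rose of 10, adjusted p = 0.963) the median was -0.31 and the mean -0.588 while the test pointed up. Nor did tear proteins (4 rose and 3 fell of 18, adjusted p = 0.343), fluid secretion machinery (1 fell of 28, adjusted p = 0.835, median 0.054, mean -0.02) or immediate early genes (4 rose and 1 fell of 29, adjusted p = 0.365) pass. The same held for extracellular matrix (3 rose of 28, adjusted p = 0.0613), nuclear oxidative phosphorylation (2 of 39, adjusted p = 0.835) and ribosomal proteins (5 of 82, adjusted p = 0.101).

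Outside the acini of MRL/lpr the interferon gamma list rose for 12 of 16 in ductal cells (camera adjusted p = 1.35e-26, adjusted p = 0.0187 with an estimated correlation) and 17 of 19 in myoepithelial cells (adjusted p = 4.45e-58, adjusted p = 0.00659 with an estimated correlation). It rose for 17 of 19 in fibroblasts (adjusted p = 4.45e-58, adjusted p = 0.00182 with an estimated correlation) and 13 of 18 in endothelial cells (adjusted p = 2.89e-33, adjusted p = 0.00486 with an estimated correlation). In macrophages 12 of 18 rose and 1 fell (adjusted p = 2.3e-11, adjusted p = 0.0213 with an estimated correlation). Here most rising members were in their own class: 9, 15, 16, 13 and 10. For these classes that condition keeps out mainly acinar RNA, so RNA from other non-acinar cells stayed open. H2 genes rose for 12 of 14 in ductal, 13 of 14 in myoepithelial, 11 of 13 in fibroblast and 10 of 14 in endothelial cells. Antigen presentation genes rose for 12 of 18, 12 of 17, 12 of 18 and 9 of 15 in the same classes. All 8 results passed with an estimated correlation as well (highest adjusted p = 0.017). Type I interferon genes rose for 19 of 21 in myoepithelial cells (adjusted p = 1.76e-32, adjusted p = 0.0243 with an estimated correlation). They rose for 15 of 26 in ductal cells (24 adjusted over the list alone, adjusted p = 4.36e-15, adjusted p = 0.21 with an estimated correlation) and 11 of 26 in fibroblasts (adjusted p = 5.38e-19, adjusted p = 0.055 with an estimated correlation). Chemokines and cytokines rose for 8 of 18 in ductal cells (adjusted p = 2.42e-09, adjusted p = 0.017 with an estimated correlation) and 6 of 20 in fibroblasts (adjusted p = 1.19e-07, adjusted p = 0.00978 with an estimated correlation).

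Named genes that changed in MRL/lpr are given here by class. The H2 haplotypes of MRL/lpr and BALB/cJ differ, so mapping alone could move H2 counts, H2-DMb1 and H2-DMb2 among them. In ductal cells H2-DMb1 (ENSMUSG00000079547, 17:34153072–34160230) rose by 8.08 (adjusted p = 8e-16; 219.3 ± 16.0 against 0.701 CPM), Iigp1 by a ratio of 1120 (200–44300) and Ly6e by 6.59 (adjusted p = 0.000439). In myoepithelial cells Ubd (ENSMUSG00000035186, 17:37193892–37196095), a ubiquitin-like protein induced by interferon, was at least 139-fold higher, Cd44 was higher by a ratio of 312 (106–1520) and Gbp4 by 135 (36.8–1120). In endothelial cells Ubd was at least 210-fold higher (412 ± 98.8 CPM), H2-DMb2 was higher by a ratio of 194 (34.1–7730) and Cxcl9 by 125 (42.4–613). In fibroblasts Cxcl9 (ENSMUSG00000029417, 5:92321347–92328079) rose by 7.30 (adjusted p = 0.00045; 166.4 ± 112.4 against 0.768 CPM). Gbp8 rose by 5.23 (adjusted p = 9.32e-11) and the urokinase Plau fell by 4.71 (adjusted p = 9.25e-07). In Krt14-high cells H2-DMb1 was higher by a ratio of 372 (65.8–14800).

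T cells of MRL/lpr glands held Lag3 (ENSMUSG00000030124, 6:124904361–124911705) at 271.8 ± 54.0 CPM against 0, at least 16.2-fold, and Gzmb was higher by a ratio of 37.2 (6.67–1470). Ramp1 (-4.31, adjusted p = 6.11e-05) and H2-Q7 (-3.39, adjusted p = 7.01e-05) fell. T cell activation and exhaustion genes rose for 4 of 16 in T cells (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.000297, adjusted p = 0.186 with an estimated correlation). Of T cell genes 33 passed, 10 without MRL/lpr replicate 2 and 12 without BALB/cJ female replicate 3. Macrophages gained Serpina3g (7.48, adjusted p = 8.43e-06), Cxcl9 (7.22, adjusted p = 6.45e-05) and Ly6a (6.86, adjusted p = 6.39e-08). They lost Siglech (-6.17, adjusted p = 5.6e-12) and Crym (-6.14, adjusted p = 5.6e-12), between clusters that differ in part. In macrophages chemokines and cytokines rose for 4 and fell for 9 of 21 (adjusted p = 0.0494, adjusted p = 0.534 with an estimated correlation). Immediate early genes rose for 2 and fell for 12 of 29 (adjusted p = 0.00256, adjusted p = 0.265 with an estimated correlation). Proliferation genes rose for 6 of 15 (adjusted p = 0.0017, adjusted p = 0.382 with an estimated correlation).

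Genes that passed in MRL/lpr numbered 1022 in ductal (619 up, 403 down), 481 in myoepithelial (281 and 200), 495 in fibroblast (336 and 159), 330 in endothelial (202 and 128), 1069 in macrophages (499 and 570) and 274 in Krt14-high cells. Without MRL/lpr replicate 2 these were 413, 233, 192, 163, 565 and 118, and without replicate 1 the endothelial count was 201 and the Krt14-high count 181. The tropomyosin-like Tpm3-rs7 (ENSMUSG00000058126, 14:113314608–113316754) was lower in ductal cells by a ratio of 255 (45.4–10100) and low in every class of MRL/lpr outside the acini. It is a near-identical copy of a larger family, so a strain variant would also lower its count. Of the named results in these classes, all kept their call without each library except Hist1h2al in ductal and Erdr1 in T cells. In all, 66 of 122 list pairs passed at the preset correlation, 20 with an estimated correlation and 55 by fry.

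NOD.H2b acinar cells kept the secretoglobins that led in BALB/cJ males. They expressed more of the fibrinogen gamma chain gene Fgg, the endonuclease Dnase1, the fatty aldehyde dehydrogenase Aldh3a2 and the lipocalins Obp1a and Lcn11, and less of the pheromone peptides Esp1 and Esp3 and of Ly6f. Endothelial cells expressed Glycam1, a mucin of the high endothelial venules through which lymphocytes enter. Fibroblasts expressed the apolipoproteins Apoe and Apoc1. Lipocalins took 8.85 ± 0.880% of acinar UMIs and exocrine gland-secreted peptides 3.68 ± 0.320%, with Scgb2b7 (12.4%), Scgb1b7 (10.3%), Gm1553 (8.51%) and Scgb2b2 (7.91%) on top.

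In NOD.H2b acinar cells 1234 genes passed (537 up, 697 down), 144 in their own class (78 and 66). The count was 542 without NOD.H2b replicate 1 and 567 without replicate 2. Fgg (ENSMUSG00000033860, 3:83007724–83015049) rose by 5.06 (adjusted p = 0.000103; 121.2 ± 23.3 against 3.63 ± 1.73 CPM). Dnase1 (ENSMUSG00000005980, 16:4036942–4040024) rose by 3.85 (adjusted p = 3.46e-05; 1802 ± 136 against 124.9 ± 58.5). Phyh rose by 1.98 (adjusted p = 0.000179), Aldh3a2 by 1.72 (adjusted p = 1.81e-07) and Obp1a by 1.70 (adjusted p = 0.00392; 62950 ± 775 against 19400 ± 10580). Ly6f fell by 3.53 (adjusted p = 0.00192), Baiap2l1 by 2.84 (adjusted p = 4.1e-10), Esp3 by 2.61 (adjusted p = 3.46e-05) and Esp1 by 1.87 (adjusted p = 0.00015; 283 ± 4.82 against 1034 ± 329). These 9 kept their call without each library. Sval3 (5.60; 252.7 ± 89.6 against 5.32 CPM), Esp24 (4.15), Esp36 (1.87), Esp23 (-1.56), Wfdc12 (2808 against 7967 ± 1335 CPM), Rimklb (-0.93) and the acyl-CoA synthetase Slc27a2 (-0.82) were lost in at least 1 refit. Among the refits that left out 1 library, all but Esp24, Esp36 and Sval3 were lost only without NOD.H2b replicate 1 or 2. Esp36 was also lost without BALB/cJ male replicate 1 or 4, Sval3 without BALB/cJ male replicate 1 or 3, and Esp24 whichever of the 6 libraries was left out. Over refits of all kinds, Rimklb was lost in 4 of 19. Of 59 named acinar results 22 kept their call without each library.

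Among the lists in NOD.H2b acinar cells, the unfolded protein response rose for 4 of 23 (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000475, adjusted p = 0.296 with an estimated correlation). Creld2 rose by 0.89 (adjusted p = 0.00028). Immediate early and dissociation genes fell for 6 of 29 (10 adjusted over the list alone, adjusted p = 0.000377, adjusted p = 0.462 with an estimated correlation). Klf2 (ENSMUSG00000055148, 8:72319033–72321656) fell by 2.87 (adjusted p = 0.000222) and Ier5 by 1.24 (adjusted p = 0.000299). Secretoglobins rose for 4 of 27 (adjusted p = 0.0379, adjusted p = 0.981 with an estimated correlation). Extracellular matrix genes fell for 2 of 28 (adjusted p = 0.0171, adjusted p = 0.992 with an estimated correlation). Lipocalins and major urinary proteins rose for 3 of 10 (adjusted p = 0.0659, median -0.252, mean 0.591, test up). Lcn11 rose by 1.58 (adjusted p = 0.000744; 12950 ± 439 against 4334 ± 941 CPM) and Lcn3 by 4.40 (adjusted p = 4.32e-05). In the fluid secretion machinery 1 rose and 3 fell of 28 (adjusted p = 0.359). Vipr1 fell by 1.43 (adjusted p = 0.00012) and Fxyd3 by 1.33 (adjusted p = 0.0015). Steroid-responsive genes rose for 3 and fell for 2 of 21 (adjusted p = 0.808). The metallothioneins Mt2 (2.82, adjusted p = 0.00185) and Mt1 (adjusted p = 1.4e-05) rose and Steap4 (-3.35, adjusted p = 5.07e-06) fell. Apart from the lipocalins, the pooled other cells of the same libraries had a higher CPM of each gene named in this and the next paragraph. RNA from other cells therefore stayed open for those genes.

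The interferon gamma list had 0 of 18 members past the threshold in NOD.H2b acinar cells (camera adjusted p = 0.782) and type I interferon genes 1 of 25 (fell, adjusted p = 0.822). Antigen presentation had 1 up and 1 down of 18 (adjusted p = 0.826), with Tap2 at 1.54 (adjusted p = 0.00025). H2 genes had 1 up and 1 down of 14 (adjusted p = 0.61), with H2-T22 at 1.74 (adjusted p = 4.25e-05), and chemokines 2 up and 1 down of 26 (adjusted p = 0.637). Exocrine gland-secreted peptides rose for 2 and fell for 3 of 14 (adjusted p = 0.61, median 0.061, mean -0.021) and tear proteins 1 and 3 of 18 (adjusted p = 0.698). Nuclear oxidative phosphorylation genes rose for 4 of 39 (adjusted p = 0.0732), with Cycs at 0.76 (adjusted p = 0.00125). The rest were ribosomal proteins 4 and 0 of 82 (adjusted p = 0.192), proliferation 0 of 20 (adjusted p = 0.969) and mitochondrially encoded genes 0 of 13 (adjusted p = 0.637).

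Ductal cells of NOD.H2b glands raised H2-DMb1 by a ratio of 25.6 (6.08–228) and the matrix protein Thbs1 (ENSMUSG00000040152, 2:118111876–118127133) by 3.97 (adjusted p = 0.000626; 362.9 ± 52.8 against 25.7 CPM). The cholesterol acyltransferase Soat1 rose by 3.47 (adjusted p = 5.82e-07) and the chemokine Cxcl10 by a ratio of 52.7 (13.5–452). Endothelial Glycam1 (ENSMUSG00000022491, 15:103562759–103565081) stood at 894 ± 164 CPM against 0, at least 270-fold (adjusted p = 3.7e-17), and Ubd was higher by a ratio of 230 (76.9–1130). Fibroblast Apoe (ENSMUSG00000002985, 7:19696109–19699188) rose by 3.63 (adjusted p = 5.81e-12; 40430 ± 6169 against 3266 ± 204) and its neighbour Apoc1 (ENSMUSG00000040564, 7:19689481–19692660) by 5.92 (adjusted p = 2.51e-11). Macrophage H2-M2 rose by 4.76 (adjusted p = 0.000128; 151.4 ± 54.3 against 3.92) and T cell Tnfsf8 by 2.96 (adjusted p = 0.0138). These 10 results kept their call without each library. Of the others, myoepithelial Cxcl9 (at least 20.6-fold) was lost without NOD.H2b replicate 2 (adjusted p = 0.35). All 6 named genes of that class and all 6 of the Krt14-high class were lost in at least 1 refit.

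Immune lists rose in the NOD.H2b classes outside the acini at the preset correlation only. H2 genes rose for 6 of 14 in ductal cells (camera adjusted p = 3.91e-09, adjusted p = 0.316 with an estimated correlation) and 2 of 14 in myoepithelial cells (7 adjusted over the list alone, adjusted p = 1.82e-10, adjusted p = 0.326 with an estimated correlation). They rose for 2 of 13 in fibroblasts (6 adjusted over the list alone, adjusted p = 3.71e-11, adjusted p = 0.314 with an estimated correlation). NOD.H2b carries the H2 haplotype of the mapping reference and BALB/cJ does not, so mapping alone could raise these H2 counts. Interferon gamma genes rose for 1 of 16 in ductal cells (adjusted p = 0.000935, adjusted p = 0.661 with an estimated correlation) and 1 of 19 in myoepithelial cells (5 adjusted over the list alone, adjusted p = 1.74e-08, adjusted p = 0.365 with an estimated correlation). In macrophages they rose for 1 of 18 (adjusted p = 0.000132, adjusted p = 0.316 with an estimated correlation). Genes past the threshold numbered 268 in ductal (154 up, 114 down), 92 in myoepithelial, 98 in fibroblast, 45 in endothelial, 32 in T cells, 73 in macrophages and 81 in Krt14-high cells. Without NOD.H2b replicate 2 these were 86, 21, 18, 9, 13, 24 and 17. Without replicate 1 they were 105 in ductal, 46 in myoepithelial, 37 in fibroblast, 19 in T cells, 41 in macrophages and 31 in Krt14-high cells. BALB/cJ males moved 2 of these counts: endothelial to 29 without replicate 1 or 4 and 26 without replicate 3, and T cells to 18 without replicate 3. In all, 31 of 122 list pairs passed at the preset correlation, 0 with an estimated correlation and 1 by fry.

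The 2 model strains shared part of their acinar differences from BALB/cJ. Higher in both were 146 genes (47.4 if the 2 sets were independent) and lower in both 178 (49.1), among them Baiap2l1 and Esp3. Another 76 changed in opposite directions, and the correlation of log2 fold changes was 0.202. In ductal cells 78 genes rose in both (10.3 by independence) and 53 fell in both (4.96), with 9 opposite and a correlation of 0.418. Ductal H2-DMb1 and endothelial Ubd rose in both strains. Both contrasts subtracted BALB/cJ, so a BALB/cJ variant that alters expression or mapping would appear in both. All libraries of the model strains came from the same library set, while the controls came from both sets. A difference between library sets could therefore also move both contrasts the same way. The counts by independence do not allow for either, so the overlap does not show a change shared through disease. The direct contrast set a change in females (MRL/lpr) against a change in males (NOD.H2b), so it did not separate sex from strain. A gene nearly absent in 1 sex could pass for that reason alone. The contrast found 997 acinar genes that differed between the 2 strains' changes. The count was 469 without MRL/lpr replicate 2, 479 without NOD.H2b replicate 1 and 539 without NOD.H2b replicate 2.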

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

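The check for a library apart from the rest of its group was set up after the data were seen. It covered 196 groups of library values and found 17, where about 1 in 20 would be found without any cause. Each value below is the gap of the outlying library as a share of the group's range.

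In acinar cells, BALB/cJ male replicate 4 had a lower share of exocrine gland-secreted peptides (0.972; 3.57% against 4.46 to 4.48%), and male replicate 3 had less Hp (0.849; 259.8 CPM against 303.2 to 310.9) and Lpo (0.864; 668 against 894.1 to 929.8). Male replicate 2 alone held any Pnliprp1 (1; 0.0316 CPM). Female replicate 2 alone held any Rimklb (1), Scgb1b10 (1) and Scgb2b17 (1), at 0.0183, 0.0183 and 0.0732 CPM. The value is 1 whenever every other library of the group holds 0, so very few UMIs are enough for it. Such flags say little about the library. Replicates 2 of both sexes were among the 3 libraries with few genes per deposited barcode.

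Chemokines and cytokines stood apart in 5 groups. Ccl8 in macrophages was high in BALB/cJ male replicate 4 (0.863) and Cxcl16 was low in male replicate 2 (0.915; 499.9 CPM against 887.2 to 923.1). In BALB/cJ females, Ccl7 in macrophages was high in replicate 1 (0.965; 1009 against 432.2 to 452.2), Ccl11 in fibroblasts was low in replicate 2 (0.958; 2287 against 3110 to 3145), and Il6 in pericytes was high in replicate 3 (0.856; 238.9 against 120.1 to 137.3).

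In ductal cells, male replicate 2 had less Aqp5 (0.846; 363.3 CPM against 479.1 to 500.2) and Slc12a2 (0.852; 395.4 against 566.9 to 596.7). Female replicate 4 had more Fxyd3 (0.866; 2043 against 1589 to 1650), replicate 3 had less Ltf (0.923; 9588 against 19690 to 20540) and replicate 1 less Dmbt1 (0.843; 2299 against 3405 to 3612).

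The changes of the 2 model strains differed from each other for 997 acinar genes, in a contrast that did not separate sex from strain. The unnamed cluster led by Ccr7 made up 8.987% of the cells of MRL/lpr replicate 1 and 3.24% of replicate 2. It was left out of the immune share and of all gene tests.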

How the results depend on the processing

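The refits without 3 libraries of about 100 genes per deposited barcode, with library codes 43 to 50 only, without the Car6-led clusters, and with other denominators of shares were chosen after seeing the data; the rest were set before. Over all results, 267 pairs of a result and a setting were run. Counts of genes, list pairs and classes not given here stayed within 1.5-fold.

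Acinar genes in MRL/lpr were 1169 with only the 2 groups compared and 1207 with the same library set only; leaving out single libraries gave 682 to 1793. NOD.H2b acinar genes were 656 with the same library set only and 542 to 1272 with single libraries left out. Sex acinar genes were 1706 with library codes 43 to 50 only and 2774 to 3291 without single libraries. The difference between the 2 models was 523 with the same library set only and 469 to 1147 without single libraries. DESeq2 gave 3071, 1592 and 1132 acinar genes for sex, MRL/lpr and NOD.H2b.

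In the 6 other classes, which leave out the Krt14-high cells, sex genes numbered 1575 with no filter on low counts, 215 with library codes 43 to 50 only (5 classes), and 670 to 1008 without single libraries. MRL/lpr genes were 1881 with the same library set only and 1576 to 3463 without single libraries. NOD.H2b genes were 959 with no filter, 303 with the same library set only (5 classes), 395 with at least 1000 UMIs per cell (3 classes), and 171 to 558 without single libraries.

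List pairs fell to 1, 20 and 0 with an estimated correlation, from 32, 66 and 31 for sex, MRL/lpr and NOD.H2b. By fry they were 2 for sex and 1 for NOD.H2b. Classes with a changed share were 1 for sex and 10 for MRL/lpr with TMM scaling of the cell counts, and 1 for sex among cells outside the acinar class. For NOD.H2b they were 0 with only the 2 groups compared, 0 with the same library set only and 0 with at least 1000 UMIs per cell, where MRL/lpr had 3. Without single libraries they were 0 to 1 for sex, 4 to 7 for MRL/lpr and 1 to 7 for NOD.H2b.

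The immune share difference of NOD.H2b depended on the setting. It was 14 points among cells outside the acinar class and 4.837 with the same library set only, but -5.812 with at least 1000 UMIs per cell, -2.32 without the 3 libraries of few genes, and -5.46 to 6.331 without single libraries. That of the sexes was 7.951 outside the acinar class, 1.666 with at least 1000 UMIs per cell, 4.513 with the same library set only, 5.283 without the 3 libraries and 0.8451 to 5.424 without single libraries. That of MRL/lpr was 36.73 to 45.02 without single libraries and 46.99 with the unnamed Ccr7 cluster counted as immune.

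With the replicate number as a block, list pairs of NOD.H2b were 47, and no other count moved by more than 1.5-fold. Same-numbered BALB/cJ females and males correlated at 0.506, -0.066, 0.293 and 0.554, MRL/lpr and BALB/cJ females at 0.352 and 0.464, and NOD.H2b and BALB/cJ males at 0.281 and -0.144. Female replicates 1, 3 and 4 correlated best with the male of their number and replicate 2 with male replicate 3 (0.169). Since not every pair was above 0.1, the libraries were taken to share a number only. Of 6152 refits of 320 named results, 5571 kept the call, 581 lost it and 0 reversed.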

Other observations

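Healthy BALB/cJ glands divided secretion between acini and ducts. Over the 8 BALB/cJ libraries, ductal cells led in Wfdc18 (163000 ± 29440 CPM) and in the iron-binding antimicrobial lactoferrin Ltf (19370 ± 4943), and acinar cells led in Pip (40180 ± 8558), Lcn11 (4386 ± 1265), the carbonic anhydrase Car6 (2939 ± 2906) and Lpo (756.8 ± 154.9). Lcn2 was highest in myoepithelial cells (931.1 ± 245 CPM) and lysozyme Lyz2 in macrophages (7457 ± 1409). Several genes for moving fluid took their largest share of RNA in ducts. The water channel Aqp5 stood at 515.9 ± 93.9 CPM in ductal and 129.7 ± 68.2 in acinar cells. These are shares of each class's RNA: ductal clusters held medians of 5180 and 1817 UMIs per cell and BALB/cJ acinar clusters 12334 to 49103, so they do not give the order per cell. The cotransporter Slc12a2 (497.4 ± 83.3), the potassium channel Kcnn4 (215.2 ± 35.9), the chloride channel Ano1 (206.2 ± 59.4) and Fxyd3 (1767 ± 243) were highest in ducts as well. Aqp1 was highest in endothelium (1406 ± 617), Aqp3 in Krt14-high cells (141.3 ± 35.6), and the muscarinic receptor Chrm3 (95.6 ± 29.5) and Aqp4 (31.3 ± 15.3) in myoepithelial cells.

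Chemokines and cytokines also differed between classes of the healthy gland, as means over both sexes. T cells held Ccl5 (5360 ± 1108 CPM), macrophages Cxcl2 (3658 ± 2066), and dendritic cells Ccl22 (201.5 ± 169). Fibroblasts held Cxcl12 (2586 ± 1093), the eosinophil chemokine Ccl11 (2523 ± 566), Cxcl14 (2109 ± 506) and the alarmin Il33 (270.8 ± 139). Ductal cells held Cxcl17 (521.6 ± 78.4), Tnf (99.4 ± 27.0) and Ccl28 (39.9 ± 8.72), and myoepithelial cells the macrophage growth factor Csf1 (146.3 ± 38.1). Pericytes held Il6 (245.0 ± 112) and Il34 (213.5 ± 51.8).

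Of the tests below, 3 were written before their results were seen (acinar RNA behind the secretoglobins, and free RNA behind the interferon gamma and cell cycle genes of MRL/lpr), and the rest were chosen after seeing the data. The secretoglobins of non-acinar male cells may be acinar RNA in their droplets. Were that so, every secretoglobin would sit at the same fraction of its acinar level within a library, and the SD of the log2 ratios was 0.2715 at the median. That fraction was 28.5 to 41.7% in BALB/cJ male replicate 2 and 2.59 to 15.1% in the other BALB/cJ males.

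Interferon gamma genes in MRL/lpr acinar cells might come from immune RNA or from doublets. Relative to other cells of the same library, the level of these genes in acinar droplets was 5.23 times that of immune markers in the lower of the 2 libraries (5.242 in the other). Markers of T cells, macrophages, plasma cells, fibroblasts, myoepithelial cells and endothelium stood at 0.6211 to 1.246% and 0.9616 to 1.89% of their level in other cells, endothelial markers highest, against 3.202 and 5.045% for these genes. The lowest ratio was 2.569, which argues against free RNA of these 6 classes. The bound set beforehand used immune markers only and did not cover other sources. Markers of ductal cells (7.6 and 15.16%), Schwann cells (3.723 and 4.22%) and NK/ILC (2.223 and 2.663%) stood higher or nearer, so free RNA of these cells stays open. In acinar cells with at most 1 immune UMI the lowest MRL/lpr library was still 6.663 times the highest BALB/cJ female library (68.1 and 111.2 CPM against 5.29 to 10.2), which argues against doublets with immune cells. A response of the acinar cells stays open, and strain background and the lpr mutation were not separated.

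Cell cycle genes in MRL/lpr acinar cells could come from cycling immune cells. Their level relative to other cells was 13.72 times that of immune markers in the lower library and 39.6 times in replicate 2. Free RNA would be spread over the acinar cells, yet 68.62% of these UMIs lay in 7 of 296 cells and 94.9% in 24 of 276, which argues against it. The 31 cycling acinar cells, 24 of them from replicate 2, had a median excess of -0.1735 immune UMIs (bootstrap interval over cells -1.14 to 0.00273). Cycling immune cells of these libraries held a median of 40, which argues against doublets with cycling immune cells. Doublets with other cycling cells were not tested. Cycling acinar cells held a median of 96760 UMIs in replicate 1 and 142300 in replicate 2, against 80860 and 80580 in the other acinar cells. Cycling cells were 2.37% and 8.70% of the MRL/lpr acinar cells, and 0 to 5 cells per library elsewhere.

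Across genes, NOD.H2b acinar changes correlated with the BALB/cJ sex difference at -0.208 (-0.234 in the other set of libraries) and MRL/lpr changes at 0.336 (0.389). The shifts were small and partial. In NOD.H2b, 59.8 and 58.7% of the genes went against the sex difference; male-high genes had medians of -0.161 and -0.261, and female-high genes 0.043 and -0.096. In MRL/lpr, 55.4 and 61.4% went with it; male-high genes had medians of 0.012 and 0.145, and female-high genes -0.142 and -0.194.

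The 8 BALB/cJ libraries can be split 4 against 4 in 35 ways. For the sex difference in acinar cells only 1 of 35 splits, the real one, gave 3360 genes (highest other 0). In the other classes only the real one gave 985 (highest other 15). By chance alone the real split would give the most genes in 1 of 35 cases, the lowest share this comparison can reach, so chance is not excluded. Every other split mixed the sexes, so a sex difference would widen its spread and lower its count. The gap to the other splits therefore does not measure the strength of the result. For gene lists 11 of 35 splits gave 32 pairs or more (highest other 58, the split by library code set), so chance cannot be excluded for these. For cell shares the real split called 0 classes, so 35 of 35 gave at least as many (highest other 1) and the comparison decides nothing.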
